A study of Homo sapiens with 8 samples.

How the data were processed

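Total RNA of SupB15 cells was measured in 8 libraries, 2 for each of 4 treatments. The treatments were DMSO for 46 h, 1035 at 2 µM for 46 h, doxorubicin at 0.1 µM for 10 h, and 1035 at 2 µM for 36 h then doxorubicin at 0.1 µM for 10 h. Whether 1035 stayed in the medium during the last 10 h is not given in the sources used here, so the combination against 1035 and the interaction do not separate an end of exposure to 1035 from doxorubicin. Per the labels, RNA was isolated with a Versagene kit, libraries were made with a stranded TruSeq kit after depletion of ribosomal RNA by Ribo-Zero Gold, and single reads of 50 bases were read on an Illumina instrument. Per the submitters' processing notes, reads were aligned to hg19 with Novoalign 2.08.01 and tested with DESeq2 1.4.5. The read counter, its strand setting and the annotation are not given in the sources used here. Values of antisense and overlapping genes are therefore uncertain.

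The authors deposited 4 tables, 1 per comparison of 2 groups, and per the file headers each holds raw counts of reads per gene for 4 libraries, on which no normalization was found. The deposited FPKM values are, per the file headers and checked on the values, counts scaled by gene length and by the reads of the library, with the reads summed by the authors over the genes of the same table. The deposited log2 fold changes are those of the authors, with the first named group as numerator. The deposited adjusted p-value of each gene is that of the authors' own comparison, and it was exactly 1 for all genes below a mean normalised count of 412 in the combination against 1035, 15.8 in the combination against doxorubicin, 13.6 in 1035 against DMSO and 993 in doxorubicin against DMSO. These genes numbered 10308, 2543, 2609 and 12579, so a value of 1 does not speak to a single gene. The tables held 17180, 16950, 17394 and 16773 genes, and the smallest total of 4 counts in any table was 10. Counts alone were used for the tests, and the authors' adjusted p-values were counted beside them.

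The tables were joined by gene identifier. All 132880 counts held by 2 tables were equal in both. Of 17849 genes in any table, 16608 had counts in all 8 libraries and were kept. The other 1241 were left out because a gene absent from a table has no count there. Their mean count had a median of 5.5, and they held at most 1.02% of a library's reads. Among symbols, 84 were shared by several identifiers, 217 in all, so genes were followed by identifier. Depth was 16217438 and 15570301 reads for DMSO, 13725592 and 12055472 for 1035, 18144670 and 12398192 for doxorubicin, and 12934237 and 11760542 for the combination.

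Groups came from the sample labels. Per the design text, the 2 samples of a treatment are independent. The p-values rest on the spread between samples of a treatment, pooled over all 4 groups and drawn toward that of other genes (median prior of 35.6 degrees of freedom). This spread differed by group. Against sampling noise, its chi-square per degree of freedom was 1.96 in DMSO, 3.51 in 1035, 5.44 in doxorubicin and 2.51 in the combination. Comparisons with the doxorubicin group thus borrow from groups with less spread. Comparisons were 1035 against DMSO, doxorubicin against DMSO, 1035 then doxorubicin against 1035, against doxorubicin and against DMSO, and the interaction, that is, the effect of 1035 with doxorubicin minus that without. Genes were filtered with filterByExpr of edgeR 4.0.16 (R 4.3.3), which removed 288 and left 16320. Counts were normalised by TMM and fitted with the robust quasi-likelihood model of edgeR to all 8 libraries with 4 group means. This left 4 residual degrees of freedom, and the common biological coefficient of variation was 4.57%. The two-sided quasi-likelihood F-test was adjusted by Benjamini-Hochberg over all genes of a comparison at an FDR of 0.05. The largest median log2 fold change of all genes in a comparison was 0.01 in size. Tested on simulated data with 200 changed genes, this test recovered 87% to 90% of 1.5-fold changes in the comparisons of groups and 73% in the interaction, and 98% to 100% and 94% of 2-fold changes. The changed genes were drawn from those with a mean normalised count of at least 50. There were 13 to 18 false calls among 201 to 206 calls in the comparisons of groups, and 21 among 188 in the interaction. The share of false calls was thus above the FDR of 0.05 in each comparison of this simulation.

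The 29 gene lists, the tests, the named-gene rule and the main alternatives were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 at a correlation between genes of 0.01, adjusted over all lists of a comparison, and also with an estimated correlation and with fry. In 1035 against DMSO, doxorubicin against DMSO, the combination against 1035, against doxorubicin and against DMSO, and the interaction, camera called 15, 12, 11, 17, 16 and 10 lists. In simulated data camera found a list of 30 genes raised 1.2-fold. Genes varied independently of each other in these data, so this does not test the preset correlation. The named genes were, per comparison, the 6 largest rises and 6 largest falls past the FDR with a mean normalised count of at least 50 and no overlap between groups, up to 4 members of each described list with the smallest adjusted p, and a fixed set of genes (among them HDAC1, HDAC2, HDAC3, CDKN1A, MDM2, TOP2A, BCR and ABL1). For the interaction they were the 6 genes with the smallest adjusted p. Members that moved against the rest of their list, and the families of genes in the closing section, were named after their values were seen. Values per group are means and SD of CPM (TMM-normalised counts scaled to a common library size), and values with a fold change are its standard error.

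Alternatives were DESeq2 1.42.0, its size factors in edgeR, the likelihood ratio test, limma-voom, no filter, a mean normalised count of at least 50, an FDR of 0.01, a fold change of at least 2, the 2 compared groups alone, a replicate block, each library left out in turn, and the authors' adjusted p-values. Leaving out library 2 of 1035 and library 2 of doxorubicin together was added after the data were seen, as was the average effect of doxorubicin without and after 1035, by which genes were chosen for a test of the interaction. Where a group was left with 1 library, that library was assumed to vary like the other groups. Groups of 2 are too small for an outlier rule or for other splits of the samples. Gene positions and types came from GENCODE release 29 on GRCh38, which held 95.96% of the tested identifiers, while the counts came from hg19. Gene lengths were those implied by the deposited counts and FPKM values, and 99.94% of genes had one. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.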

Results

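SupB15, an established human cell line from a pre-B acute lymphoblastic leukemia that carries the Philadelphia chromosome, was profiled by total RNA sequencing in 4 groups of 2 libraries each. Cells received the solvent DMSO for 46 h, 2 µM of the compound 1035 for 46 h, 0.1 µM doxorubicin for 10 h, or 2 µM 1035 for 36 h followed by 0.1 µM doxorubicin for 10 h. The series title calls 1035 a histone deacetylase (HDAC) inhibitor, that is, a drug that blocks removal of acetyl groups from histones. Doxorubicin is an anthracycline that traps topoisomerase II and breaks DNA. The counted reads on the genes shared by all libraries numbered 16217438 and 15570301 for DMSO, 13725592 and 12055472 for 1035, 18144670 and 12398192 for doxorubicin, and 12934237 and 11760542 for the combination. On the first principal component, which held 83.1% of the variance over 12073 genes, the 4 libraries given 1035 lay between 25.2 and 27.8 and the 4 others between -29.2 and -23.6.

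The effect of 1035 alone was asked in 1035 against DMSO. EIF4E3, a translation factor of the eIF4E family that binds the mRNA cap, rose from 0.583 ± 0.0766 to 9.41 ± 0.434 CPM (TMM-normalised counts scaled to a common library size, mean ± SD, n = 2 here and below). NES, which encodes the intermediate filament nestin, rose from 0.741 ± 0.394 to 11.1 ± 0.787 CPM, and SUCNR1, the receptor for succinate, rose from 0.908 ± 0.0681 to 12.3 ± 0.510 CPM. AVEN, an inhibitor of apoptosis that binds Apaf-1, fell from 26.0 ± 0.402 to 4.53 ± 0.605 CPM. IGLL1, the lambda5 part of the surrogate light chain that precursor B cells display, fell from 851 ± 21.5 to 244 ± 30.3 CPM. In the edgeR quasi-likelihood test, 3944 of 16320 genes rose and 4049 fell at a Benjamini-Hochberg false discovery rate (FDR) of 5%. Of these, 1142 rose and 338 fell by at least 2-fold. The other largest rises were FXYD7 (log2 fold change 3.86 ± 0.24, SE), the pseudogene FER1L4 (3.57 ± 0.24) and DACT3 (3.57 ± 0.28), an inhibitor of Wnt signalling. The other largest falls were the aldehyde oxidase pseudogenes AOX2P (-2.63 ± 0.21) and AOX3P (-2.29 ± 0.26), LRRC26 (-2.09 ± 0.21), USP41 (-2.07 ± 0.25) and KNDC1 (-2.05 ± 0.23). Reads on AOX2P and AOX3P, on USP41 and on FER1L4 can be shared with their paralogs.

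Genes of chromosome replication and cell division were lower after 1035. Of the 38 tested genes of G1/S and DNA replication, 35 fell and 3 did not pass the test (36 adjusted over the list alone; camera adjusted p = 7.0e-16, adjusted p = 0.191 with an estimated correlation). CCNE2, a cyclin that starts S phase, had a log2 fold change of -1.07 ± 0.07, RRM2, a subunit of ribonucleotide reductase, -0.87 ± 0.06, and MCM7, part of the replicative helicase, -0.77 ± 0.06. Replication-dependent histone genes, which are transcribed in S phase, fell for 51 of 52 members (51 adjusted over the list alone; camera adjusted p = 1.5e-45, adjusted p = 0.191 with an estimated correlation). HIST1H2AB had a log2 fold change of -1.37 ± 0.06 and HIST1H2BO of -1.17 ± 0.06, although short reads from these similar genes can be assigned to the wrong member. Of 38 genes of G2/M and mitosis, 31 fell, 1 rose and 6 did not pass (1 higher and 31 lower adjusted over the list alone; camera adjusted p = 2.9e-07, adjusted p = 0.265 with an estimated correlation). The mitotic genes HMMR and CCNB2 had log2 fold changes of -0.62 and -0.63, while PTTG1, which encodes the separase inhibitor securin, rose by 0.21. Among targets of MYC and genes of ribosome biogenesis, 26 of 30 fell and 4 did not pass (27 adjusted over the list alone; camera adjusted p = 2.0e-11, adjusted p = 0.199 with an estimated correlation). ODC1, which makes putrescine, had a log2 fold change of -1.23 ± 0.06 and CAD, which starts pyrimidine synthesis, -0.84 ± 0.06. MYC itself had a log2 fold change of -0.31 (adjusted p = 2.4e-05, edgeR).

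Most genes of homologous recombination and of the damage checkpoint were lower too. Of 35 genes of homologous recombination and resection, 25 fell, 2 rose and 8 did not pass (2 higher and 25 lower adjusted over the list alone; camera adjusted p = 6.7e-07, adjusted p = 0.143 with an estimated correlation). NBN, a subunit of the complex that senses DNA breaks, had a log2 fold change of -1.08 ± 0.06 and BRCA2, which acts in strand exchange, -0.78 ± 0.06. RAD51B (0.49) and RAD50 (0.31) rose. Of 22 genes of the DNA damage checkpoint, 13 fell, 2 rose and 7 did not pass (2 higher and 14 lower adjusted over the list alone; camera adjusted p = 6.4e-04, adjusted p = 0.2 with an estimated correlation). The checkpoint kinase gene CHEK1 had a log2 fold change of -0.68 ± 0.06 and CLSPN, its adaptor, -0.67 ± 0.06. MDC1 (0.26), which binds marked chromatin at breaks, and RAD9A (0.51), part of a checkpoint clamp, rose. Non-homologous end joining was mixed, with 4 of 19 genes higher and 8 lower (4 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.154). LIG3 (-0.62) fell and TP53BP1 (0.42), which shields broken ends from resection, rose. Of 31 p53 target genes, 20 fell, 5 rose and 6 did not pass (6 higher and 20 lower adjusted over the list alone; camera adjusted p = 0.0089, adjusted p = 0.503 with an estimated correlation). TRIM22 (-1.09 ± 0.06) and AEN (-0.93 ± 0.09) fell. The 5 that rose were CDKN1A (0.29 ± 0.06), which encodes the cell cycle inhibitor p21, BTG2 (1.02 ± 0.07), TP53INP1 (0.69 ± 0.06), TNFRSF10B (1.34 ± 0.13) and CYFIP2 (0.23 ± 0.06). MDM2, which encodes a ubiquitin ligase, fell by 0.30 on the log2 scale.

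**Figure D1:**
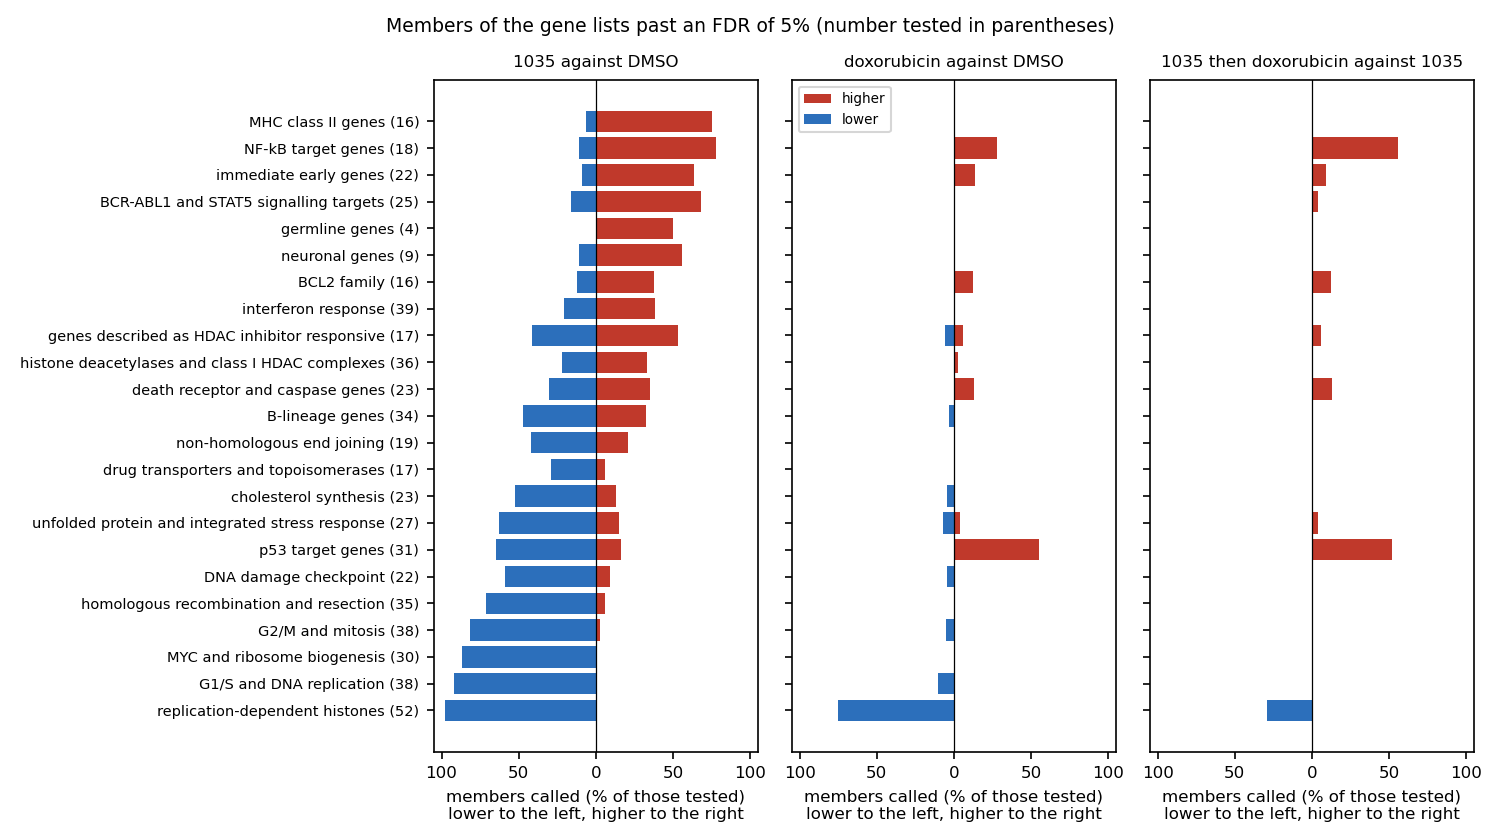
Share of the tested members of the gene lists, leaving out those of cell-type markers, ribosomal proteins and mitochondrially encoded genes, past an FDR of 5% (x axis, percent), drawn to the right of 0 for members that were higher and to the left for members that were lower, in 3 comparisons of 2 against 2 libraries. In 1035 against DMSO 51 of 52 replication-dependent histones were lower, and 17 of 31 p53 target genes were higher in doxorubicin against DMSO.

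Several groups of immune genes were higher after 1035. Of 18 NF-kB target genes, 14 rose, 2 fell and 2 did not pass (14 higher and 2 lower adjusted over the list alone; camera adjusted p = 9.0e-06, adjusted p = 0.191 with an estimated correlation). The cytokine gene TNF rose from 7.41 ± 0.469 to 30.8 ± 0.164 CPM, and CD40, a costimulatory receptor of B cells, had a log2 fold change of 2.14 ± 0.15. The 2 that fell were NFKB1 (-0.64 ± 0.06), a subunit of NF-kB, and NFKBIA (-0.48 ± 0.07), its inhibitor. Of 16 MHC class II genes, 12 rose, 1 fell and 3 did not pass (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.4e-04, adjusted p = 0.323 with an estimated correlation). HLA-DMA, from 39.6 ± 1.31 to 84.6 ± 7.04 CPM, and HLA-DOB (1.53 ± 0.20), which control peptide loading, and the master regulator CIITA (0.53 ± 0.06) rose. RFX5, which binds class II promoters, had a log2 fold change of -0.45 ± 0.06. Of 22 immediate early genes, 14 rose, 2 fell and 6 did not pass (15 higher and 2 lower adjusted over the list alone; camera adjusted p = 3.8e-06, adjusted p = 0.199 with an estimated correlation), with FOS at 1.60 ± 0.16 and IER2 at 0.97 ± 0.08. DUSP1 (-0.25), a phosphatase of MAP kinases, and MYC were the 2 that fell. Interferon response genes went both ways, with 15 of 39 higher, 8 lower and 16 not past the test (16 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.0923). IFITM1 (0.97 ± 0.08) and STAT2 (0.77 ± 0.06) rose, whereas IRF7 (-1.18 ± 0.11), a transcription factor of the interferon response, fell.

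Lineage and signalling genes changed in both directions. Of 34 B-lineage genes, 11 rose, 16 fell and 7 did not pass (12 higher and 16 lower adjusted over the list alone; camera adjusted p = 0.147). DNTT (-0.88 ± 0.06), which adds bases at antigen receptor joints, fell with IGLL1, while MS4A1 (1.01 ± 0.06), which encodes CD20, and CD22 (0.80 ± 0.06) rose. Of 25 genes downstream of BCR-ABL1 and STAT5, 17 rose, 4 fell and 4 did not pass (18 higher and 4 lower adjusted over the list alone; camera adjusted p = 6.4e-05, adjusted p = 0.143 with an estimated correlation). CCND2 (2.02 ± 0.18), a cyclin, PIM1 (1.37 ± 0.13), a kinase, and SPRY4 (1.17 ± 0.11), an inhibitor of Ras signalling, rose. The 4 that fell were CCND3 (-0.55), OSM (-1.56), STAT5B (-0.18) and MYC. BCR (0.01 ± 0.06, adjusted p = 0.895, edgeR) did not pass the test. ABL1 (0.14 ± 0.06, adjusted p = 0.0479) passed, but not with single libraries left out (adjusted p): ABL1 without 1035 library 2 (0.229), combination library 1 (0.0555), combination library 2 (0.0555), DMSO library 1 (0.0983) or DMSO library 2 (0.283), nor with DESeq2 (0.0719), its size factors in edgeR (0.0509), the likelihood ratio test (0.0589) or without library 2 of 1035 and library 2 of doxorubicin together (0.105).

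Of all members of the fixed lists, a cell death gene had the smallest p-value. BMF, a BH3-only protein that promotes apoptosis, rose from 66.8 ± 0.914 to 253 ± 8.65 CPM (adjusted p = 1.6e-25, edgeR). Of 16 genes of the BCL2 family, 6 rose, 2 fell and 8 did not pass (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0546). BNIP3L (0.87 ± 0.07) rose, and the pro-apoptotic genes BAX (-0.54 ± 0.08) and BID (-0.60 ± 0.09) fell. Of 23 death receptor and caspase genes, 8 rose, 7 fell and 8 did not pass (8 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.477). The TRAIL receptor genes TNFRSF10A (2.44 ± 0.34) and TNFRSF10B rose, and FAS (-0.97 ± 0.30) fell.

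The targets of the compound class and metabolic genes were also examined. Of 36 genes of histone deacetylases and class I HDAC complexes, 12 rose, 8 fell and 16 did not pass (12 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.915). The median (0.01) and the mean (0.10) of this list were positive while camera's direction was down. HDAC1 (0.32 ± 0.06) and HDAC3 (0.31 ± 0.06) rose, and HDAC2 stood at -0.13 ± 0.06 (adjusted p = 0.0691, edgeR). MBD3 (-0.97 ± 0.07) and CHD3 (-0.78 ± 0.06), parts of the NuRD complex, fell. Of 17 genes described as responsive to HDAC inhibitors, 9 rose, 7 fell and 1 did not pass (9 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.375). The actin-severing gene GSN (1.66 ± 0.07) and TXNIP (0.65 ± 0.07) rose, and CTPS1 (-0.71 ± 0.06), which makes CTP, fell. In the list of the unfolded protein and integrated stress response, 17 of 27 genes fell, 4 rose and 6 did not pass (4 higher and 17 lower adjusted over the list alone; camera adjusted p = 9.0e-06, adjusted p = 0.191 with an estimated correlation). The members with the smallest p-values were PHGDH (-1.13 ± 0.06), PSAT1 (-0.93 ± 0.07) and MTHFD2 (-1.02 ± 0.06), enzymes of serine synthesis and one-carbon metabolism. The 4 that rose were DDIT4 (0.40), XBP1 (0.47), PPP1R15A (0.53) and ERN1 (0.49), of which ERN1 encodes the sensor IRE1 that splices XBP1. Of 23 genes of cholesterol synthesis, 12 fell, 3 rose and 8 did not pass (3 higher and 12 lower adjusted over the list alone; camera adjusted p = 0.00772, adjusted p = 0.405 with an estimated correlation), with ACAT2 at -0.90 ± 0.07, whereas MVD (0.24), INSIG1 (0.17) and TM7SF2 (0.28) rose. Of 17 drug transporter and topoisomerase genes, 5 fell, 1 rose and 11 did not pass (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.319). TOP2A, the target of doxorubicin in dividing cells, had a log2 fold change of -0.17 ± 0.06 (adjusted p = 0.0146, edgeR). This call ended with single libraries left out (adjusted p): TOP2A without 1035 library 2 (0.0612), DMSO library 1 (0.143) or DMSO library 2 (0.0663), and also with all libraries over genes with a mean normalised count of at least 50 (0.0534).

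Markers of other cell types were measured beside these groups. Of 9 stromal and fibroblast markers, 7 rose and 2 did not pass (7 adjusted over the list alone; camera adjusted p = 6.4e-04, adjusted p = 0.202 with an estimated correlation). PDGFRB, a growth factor receptor, rose from 26.4 ± 1.38 to 66.2 ± 3.20 CPM and the collagen gene COL1A1 from 0.229 ± 0.144 to 2.24 ± 0.624 CPM. Of 9 neuronal genes, 5 rose, 1 fell and 3 did not pass (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.174), with ENO2 at 2.46 ± 0.22 and TUBB3, whose symbol the files give to more than 1 identifier, at -1.34 ± 0.10. Of 4 germline genes, TDRD1 (1.97 ± 0.19) and PRAME rose and 2 did not pass (2 adjusted over the list alone; camera adjusted p = 0.0162, adjusted p = 0.199 with an estimated correlation). PRAME, a cancer-testis antigen, had 0 counts in both DMSO libraries and 3.46 ± 0.621 CPM after 1035. Of 9 myeloid markers, 5 rose, 2 fell and 2 did not pass (5 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.432), with MPO at 0.99 ± 0.14. Among 5 T and NK cell markers TCF7 rose (3.45 ± 0.21), ZAP70 fell (-0.72 ± 0.07), LAT rose and 2 did not pass (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.416). LAT (0.93 ± 0.34, adjusted p = 0.0222, edgeR) did not pass with single libraries left out (adjusted p): LAT without 1035 library 2 (0.291) or DMSO library 2 (0.168), nor with DESeq2 (0.146), by the authors' deposited adjusted p (0.135) or without library 2 of 1035 and library 2 of doxorubicin together (0.258). Among 3 erythroid and megakaryocyte markers EPOR rose (1.54 ± 0.27), TFRC fell (-0.60 ± 0.06) and 1 did not pass (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.453). The median log2 fold change of these 3 was -0.20 and camera's direction was down, while their mean was 0.25. Of 40 ribosomal protein genes, 4 rose, 11 fell and 25 did not pass (3 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.432). The 15 mitochondrially encoded genes did not pass, the smallest adjusted p being that of MT-CO1 (0.51 ± 0.19, adjusted p = 0.0995, edgeR; camera over the list adjusted p = 0.2). Library 2 of 1035 held 2316 reads on MT-ND6 against 355 in library 1, and the share of reads on MALAT1, a nuclear RNA, was 0.249% and 0.250% in DMSO and 0.665% and 0.544% in 1035. By abundance, the median log2 fold change was 0.38 in the tenth of genes with the lowest mean counts and -0.12 in the tenth with the highest. In 1035 then doxorubicin against doxorubicin these medians were 0.08 (bootstrap 95% interval 0.03 to 0.11), below the 0.15 of the genes next in abundance, and -0.09. In 1035 then doxorubicin against DMSO they were 0.28 and -0.13.

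The response to doxorubicin alone was asked in doxorubicin against DMSO. The labels give 46 h of DMSO but 10 h of doxorubicin, so length of treatment is not separated from the drug here or in the interaction. The combination against doxorubicin carries the same difference. PLK2, a stress-induced kinase, rose from 12.5 ± 1.06 to 30.8 ± 4.58 CPM. PHLDA3, an inhibitor of AKT, rose from 5.01 ± 0.590 to 12.3 ± 0.627 CPM and ZMAT3, an RNA-binding protein, from 55.4 ± 3.56 to 106 ± 2.20 CPM. CDKN1A rose from 189 ± 4.66 to 281 ± 11.4 CPM, and the histone gene HIST1H2AB fell from 257 ± 16.5 to 186 ± 9.56 CPM. In edgeR's test 128 of 16320 genes rose and 89 fell at an FDR of 5%, and 16 rose at least 2-fold. DESeq2 had 57 higher and 96 lower, but gave no adjusted p for 11592 of its 16608 genes in this comparison. The authors' deposited adjusted p gave 23 higher and 57 lower, with a limit given below. Methods that gave every tested gene an adjusted p had more higher than lower genes. They were DESeq2's size factors in edgeR (125 and 88), the likelihood ratio test (173 and 99) and limma-voom (102 and 97). The other largest rises were the long non-coding RNA LINC01021 (log2 fold change 1.19 ± 0.13), SULF2 (1.16 ± 0.16), a sulfatase of heparan sulfate, and VWCE (0.90 ± 0.16). The other largest falls were SHISA2 (-0.50 ± 0.11), the small nucleolar RNA SNORA48 (-0.47 ± 0.11), HIST1H3H (-0.46 ± 0.08), HIST1H4K (-0.46 ± 0.10) and IGJ (-0.41 ± 0.07), the joining chain of antibodies.

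Of 31 p53 target genes, 17 rose and 14 did not pass (26 adjusted over the list alone; camera adjusted p = 4.0e-61, adjusted p = 0.0707 with an estimated correlation). SESN1 (0.62 ± 0.08), a sestrin that inhibits mTORC1, was among them. MDM2 passed at 0.22 ± 0.06 (adjusted p = 0.0389, edgeR). The list held 10 higher genes without library 1 or 2 of DMSO, 9 with DESeq2 and 8 by the authors' deposited adjusted p. Of 18 NF-kB target genes, 5 rose and 13 did not pass (10 adjusted over the list alone; camera adjusted p = 1.9e-16, adjusted p = 0.0707 with an estimated correlation). NFKB2 (0.85 ± 0.11) and RELB (0.77 ± 0.12) of the alternative NF-kB pathway rose, as did NFKBIA, from 97.3 ± 1.64 to 128 ± 5.34 CPM. BIRC3, an inhibitor of apoptosis, stood at 0.0661 ± 0.0935 CPM in DMSO and 1.41 ± 0.0580 CPM after doxorubicin. In this list 8 members were higher without library 1 of doxorubicin, 2 with DESeq2 and 1 by the authors' deposited adjusted p. Among the raised p53 targets were BBC3 (0.88 ± 0.11), which encodes the BH3-only protein PUMA, and TNFRSF10B (0.88 ± 0.13). DESeq2 gave no adjusted p for 11592 of 16608 genes in this comparison. Its counts for the gene lists leave out any members among these, so a smaller count is not a test of those members.

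Histone genes were lower after doxorubicin. Of 52 replication-dependent histone genes, 39 fell and 13 did not pass (48 adjusted over the list alone; camera adjusted p = 2.8e-72, adjusted p = 0.183 with an estimated correlation). HIST1H4I had a log2 fold change of -0.41 ± 0.06. Without library 1 of DMSO 2 of them were lower, without library 2 of DMSO 19, and without library 2 of doxorubicin 21. Of 38 genes of G1/S and DNA replication, 4 fell and 34 did not pass (1 higher and 22 lower adjusted over the list alone; camera adjusted p = 5.9e-13, adjusted p = 0.3 with an estimated correlation). This count was 7 with DESeq2, 1 with the 2 compared groups alone, 7 without either library of 1035, 13 without library 1 of doxorubicin, 1 without library 2 of doxorubicin or either library of the combination, and 0 without either DMSO library. HDAC1 (-0.10), HDAC2 (-0.09), HDAC3 (0.02), TOP2A (-0.12), BCR (-0.08) and ABL1 (0.04) did not pass.

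The number of genes called depended on single libraries. It was 33 without library 1 of DMSO, 65 without library 2 of DMSO, 1180 without library 1 of doxorubicin, 98 without library 2 of doxorubicin, and 116 without either library of the combination. Of the genes named here, these lost their call with single libraries left out (edgeR, adjusted p): VWCE without DMSO library 1 (0.162), SHISA2 without DMSO library 1 (0.254), DMSO library 2 (0.0947) or doxorubicin library 2 (0.254), SNORA48 without DMSO library 1 (0.407) or doxorubicin library 2 (0.144), HIST1H3H without DMSO library 1 (0.0804), HIST1H4K without DMSO library 1 (0.389) or doxorubicin library 2 (0.225) and MDM2 without combination library 1 (0.0654), combination library 2 (0.0694), DMSO library 1 (0.486), DMSO library 2 (0.302) or doxorubicin library 1 (0.0989). Without library 2 of 1035 and library 2 of doxorubicin together SHISA2 (0.143), SNORA48 (0.0651) and HIST1H4K (0.102) did not pass. By the authors' deposited adjusted p, HIST1H3H (0.0905), and PLK2, PHLDA3, LINC01021, SULF2, VWCE, SHISA2, SNORA48, HIST1H4K, BBC3, TNFRSF10B, BIRC3, NFKB2 and RELB (each 1) did not pass, with the signs above. This value was 1 for all 12579 of the authors' 16773 genes with a mean normalised count below 993 and for no other, so it does not speak to single genes.

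**Figure D2:**
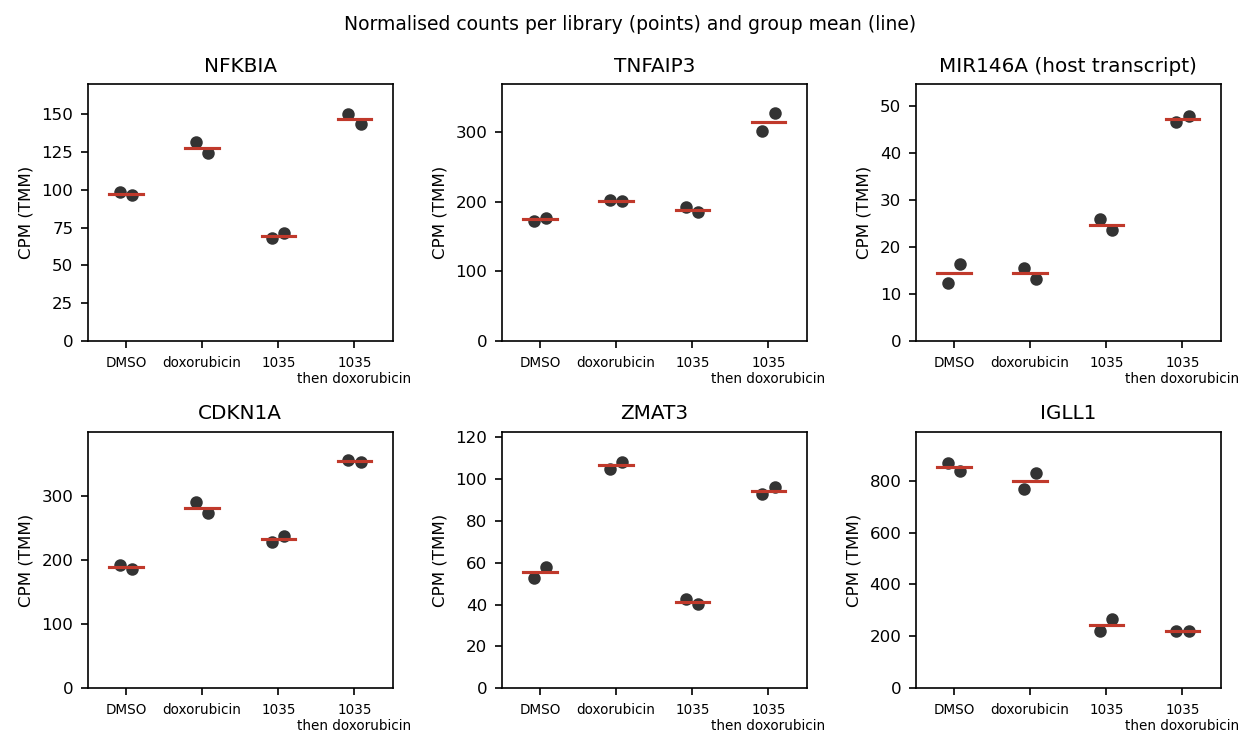
TMM-normalised counts scaled to a common library size (CPM, y axis, from 0) of 6 genes in each of the 8 libraries (points) by group (x axis), with the group mean as a line. CDKN1A was higher with doxorubicin both without and after 1035, while NFKBIA, TNFAIP3 and the MIR146A host transcript had their highest means, 147, 314 and 47.2 CPM, after 1035 then doxorubicin.

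What doxorubicin added in cells that already had 1035 was asked in 1035 then doxorubicin against 1035. The 1035 group had the compound for 46 h and the combination for 36 h before doxorubicin, and whether it stayed for the last 10 h is not given in the sources used here, so an end of exposure to 1035 is not separated from doxorubicin in this comparison. ZMAT3 rose from 41.3 ± 1.70 to 94.4 ± 2.23 CPM, LINC01021 from 3.21 ± 0.977 to 13.1 ± 1.05 CPM and CDKN1A from 232 ± 6.07 to 353 ± 1.70 CPM. NFKBIA, the inhibitor that NF-kB induces to limit itself, rose from 69.7 ± 2.69 to 147 ± 4.76 CPM. TNFAIP3, which encodes the NF-kB-limiting enzyme A20, rose from 188 ± 4.62 to 314 ± 17.7 CPM. In edgeR's test 57 of 16320 genes rose and 24 fell at an FDR of 5%, and 13 rose at least 2-fold. PHLDA3 (1.72 ± 0.26), RGS16 (1.46 ± 0.13), a regulator of G proteins, C2CD4B (1.19 ± 0.22) and PLK2 (from 7.16 ± 0.560 to 15.3 ± 0.884 CPM) completed the largest rises. ANK1 (-0.85 ± 0.21), HIST1H2AB (-0.45 ± 0.07), HIST1H2BJ (-0.40 ± 0.06), HIST1H2AD (-0.34 ± 0.06) and HIST1H2AL (-0.34 ± 0.07) were among the largest falls.

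Of 31 p53 target genes, 16 rose and 15 did not pass (27 adjusted over the list alone; camera adjusted p = 4.0e-101, adjusted p = 0.0164 with an estimated correlation). TRIM22 (0.59 ± 0.06) and AEN (0.77 ± 0.09), both lower after 1035 alone, rose here. MDM2 stood at 0.22 ± 0.06 (adjusted p = 0.081, edgeR). Of 18 NF-kB target genes, 10 rose and 8 did not pass (13 adjusted over the list alone; camera adjusted p = 4.4e-64, adjusted p = 0.00815 with an estimated correlation), with NFKB2 at 0.97 ± 0.10 and the cytokine gene LTB at 1.08 ± 0.13. Without library 2 of the combination 6 of them were higher, and 3 by the authors' deposited adjusted p, which gave 9 of the p53 targets, 8 of the histone genes and 1 of the BCL2 family. BAX (0.53 ± 0.08) and BBC3 (0.75 ± 0.12) rose among the 16 BCL2 family genes (2 adjusted over the list alone; camera adjusted p = 0.0181, adjusted p = 0.191 with an estimated correlation). Of 52 replication-dependent histone genes, 15 fell and 37 did not pass (42 adjusted over the list alone; camera adjusted p = 3.8e-60, adjusted p = 0.19 with an estimated correlation). HDAC1 (-0.02), HDAC2 (-0.03), HDAC3 (-0.05), TOP2A (-0.06), BCR (-0.10) and ABL1 (0.01) did not pass.

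In this comparison the genes called numbered 45 without library 2 of 1035, 50 and 30 without libraries 1 and 2 of the combination, and 143 without either doxorubicin library. Lower histone genes numbered 27 without library 1 and 2 without library 2 of 1035, 4 and 1 without libraries 1 and 2 of the combination, and 28 without either doxorubicin library, and 27 with the 2 compared groups alone. They numbered 7 without library 2 of 1035 and library 2 of doxorubicin together. The named genes that lost their call with single libraries left out were (edgeR, adjusted p): C2CD4B without 1035 library 2 (0.0627), combination library 1 (0.0864) or combination library 2 (0.116), ANK1 without 1035 library 2 (0.719), combination library 1 (0.42) or combination library 2 (0.322), HIST1H2BJ without combination library 2 (0.0695), HIST1H2AD without 1035 library 2 (0.0772) or combination library 2 (0.094) and HIST1H2AL without 1035 library 2 (0.632), combination library 1 (0.0718) or combination library 2 (0.675). C2CD4B (0.071) and ANK1 (0.302) did not pass with DESeq2 either, nor ANK1 with limma-voom (0.126), nor ANK1 (0.376) and HIST1H2AL (0.13) without library 2 of 1035 and library 2 of doxorubicin together. By the authors' deposited adjusted p, HIST1H2AL (0.175), and LINC01021, PHLDA3, RGS16, C2CD4B, PLK2, ANK1, BBC3 and LTB did not pass, the last 8 at a value of 1 that all 10308 genes below a mean normalised count of 412 had.

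The effect of 1035 in cells given doxorubicin was asked in 1035 then doxorubicin against doxorubicin. SUCNR1 rose from 0.808 ± 0.114 to 14.1 ± 0.889 CPM and F3, which encodes tissue factor, from 1.96 ± 0.548 to 17.3 ± 1.53 CPM. AVEN fell from 23.1 ± 2.92 to 5.04 ± 0.933 CPM and IGLL1 from 798 ± 45.9 to 222 ± 1.47 CPM. BMF rose from 76.8 ± 1.24 to 247 ± 6.58 CPM. In edgeR's test 3560 of 16320 genes rose and 3596 fell at an FDR of 5%, and 852 rose and 340 fell at least 2-fold. The largest changes included rises of FXYD7 (4.23 ± 0.26), EIF4E3 (3.55 ± 0.28), the melanosome gene PMEL (3.35 ± 0.21) and HR (3.35 ± 0.29), which encodes the histone demethylase hairless. They included falls of AOX2P (-2.87 ± 0.22), USP41 (-2.40 ± 0.25), DMD (-2.25 ± 0.21), HERC6 (-2.15 ± 0.20) and the glycine transporter gene SLC6A9 (-2.15 ± 0.19).

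Replication-dependent histones fell for 51 of 52 members (51 adjusted over the list alone; camera adjusted p = 8.5e-43, adjusted p = 0.204 with an estimated correlation), with HIST1H2AB at -1.35 ± 0.07. Of 38 G1/S and DNA replication genes, 31 fell and 7 did not pass (33 adjusted over the list alone; camera adjusted p = 1.8e-11, adjusted p = 0.204 with an estimated correlation). Of 38 G2/M genes, 27 fell, 1 rose and 10 did not pass (1 higher and 27 lower adjusted over the list alone; camera adjusted p = 6.5e-07, adjusted p = 0.31 with an estimated correlation). Homologous recombination genes fell for 24 of 35, and 1 rose (1 higher and 24 lower adjusted over the list alone; camera adjusted p = 1.4e-05, adjusted p = 0.204 with an estimated correlation), with NBN at -0.98 ± 0.06. MYC and ribosome biogenesis genes fell for 27 of 30 (28 adjusted over the list alone; camera adjusted p = 1.8e-10, adjusted p = 0.212 with an estimated correlation). NF-kB target genes rose for 16 of 18 and 1 fell (16 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.8e-11, adjusted p = 0.118 with an estimated correlation), with TNF at 2.29 ± 0.11 and LTB at 2.00 ± 0.14. MHC class II genes rose for 11 of 16 and 1 fell (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.1e-04, adjusted p = 0.31 with an estimated correlation). Immediate early genes rose for 16 of 22 and 2 fell (17 higher and 3 lower adjusted over the list alone; camera adjusted p = 3.5e-08, adjusted p = 0.204 with an estimated correlation). Of 31 p53 target genes, 6 rose, 18 fell and 7 did not pass (6 higher and 18 lower adjusted over the list alone; camera adjusted p = 0.035, adjusted p = 0.552 with an estimated correlation). PLK2 (-1.02 ± 0.11) and TRIM22 (-0.95 ± 0.06) fell, and CDKN1A (0.33 ± 0.06) and BTG2 (0.78 ± 0.07) rose. MDM2 (-0.30 ± 0.06) fell and HDAC1 (0.40 ± 0.06) and HDAC3 (0.24 ± 0.06) rose, while HDAC2 (-0.06), TOP2A (-0.10), BCR (-0.01) and ABL1 (0.11) did not pass. The authors' deposited table of this comparison held 4436 genes at an adjusted p under 0.05, without HDAC3 (0.0524).

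**Figure D3:**
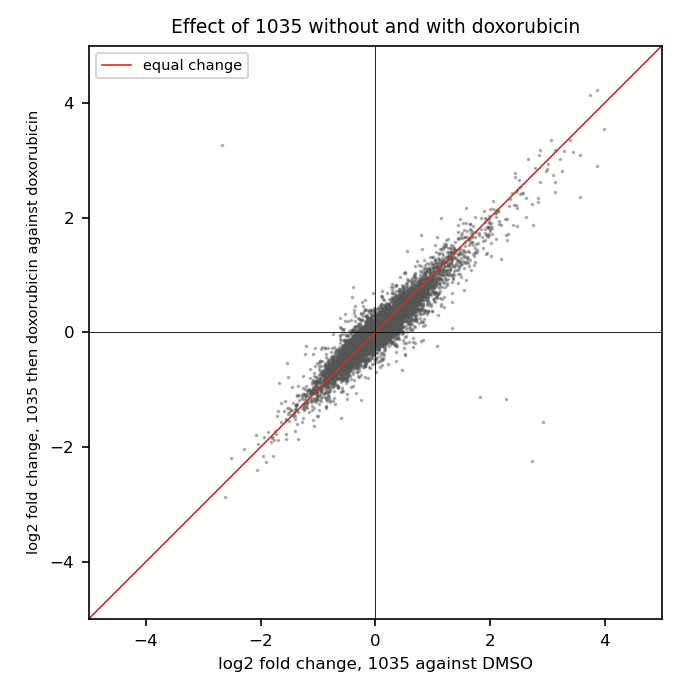
Log2 fold change of 1035 against DMSO (x axis) and of 1035 then doxorubicin against doxorubicin (y axis) for the 12073 genes (points) with a mean normalised count of at least 50, with a line at equal change. Most points lie along the line, with a Pearson correlation across genes of 0.930.

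The 2 estimates of the effect of 1035 share no library. Across 16320 genes their log2 fold changes had a Pearson correlation of 0.543 and a Spearman correlation of 0.783, and over the 12073 genes with a mean normalised count of at least 50 the Pearson correlation was 0.930. Genes are not independent replicates, so no p-value is given. There were 3023 genes higher in both, where 860 would be shared by chance, 3135 lower in both, where 892 would be, and 3 were called in opposite directions. The 2 estimates of the effect of doxorubicin, doxorubicin against DMSO and 1035 then doxorubicin against 1035, had 32 genes higher in both, where 0.447 would be shared by chance, and 18 lower in both, where 0.131 would be. Of the genes called in doxorubicin against DMSO, 95.4% had the same sign in the other. Their Pearson correlation was -0.447 over 16320 genes, 0.221 over the 12073 more abundant genes, and 0.0982 over all genes without library 2 of 1035 and library 2 of doxorubicin. Their Spearman correlation over the 16320 genes was 0.148.

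The combined treatment against the control was asked in 1035 then doxorubicin against DMSO. CCR7, a chemokine receptor that guides lymphocytes to lymph nodes, rose from 2.14 ± 0.403 to 27.1 ± 0.820 CPM. CDKN1A rose from 189 ± 4.66 to 353 ± 1.70 CPM and TNFRSF10B, a TRAIL receptor gene raised by either drug alone, from 6.78 ± 0.420 to 22.9 ± 1.24 CPM. JUN rose from 4.11 ± 0.949 to 16.2 ± 0.845 CPM, and HIST1H2AB fell from 257 ± 16.5 to 73.0 ± 1.90 CPM. In edgeR's test 3999 of 16320 genes rose and 4023 fell at an FDR of 5%, and 1096 rose and 388 fell at least 2-fold. SUCNR1 (3.94 ± 0.21), EIF4E3 (3.80 ± 0.29), FXYD7 (3.74 ± 0.24), NES (3.61 ± 0.25) and FER1L4 (3.55 ± 0.25) had the other largest rises, and AOX2P (-2.84 ± 0.22), KNDC1 (-2.37 ± 0.24), AVEN (-2.36 ± 0.14), AOX3P (-2.32 ± 0.26), USP41 (-2.21 ± 0.26) and LRRC26 (-2.16 ± 0.21) the largest falls. All 52 tested replication-dependent histone genes fell (52 adjusted over the list alone; camera adjusted p = 5.6e-72, adjusted p = 0.13 with an estimated correlation). Of 18 NF-kB target genes 17 rose and NFKB1 (-0.38 ± 0.06) fell (17 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.6e-18, adjusted p = 0.0876 with an estimated correlation). Of 22 immediate early genes 20 rose and 2 fell (20 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.1e-09, adjusted p = 0.13 with an estimated correlation). Of 31 p53 target genes 14 rose, 5 fell and 12 did not pass (14 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.00943, adjusted p = 0.427 with an estimated correlation), and MDM2 stood at -0.08 ± 0.06 (adjusted p = 0.252, edgeR). Among 16 BCL2 family genes 8 rose and BID (-0.57 ± 0.09) fell (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00943, adjusted p = 0.138 with an estimated correlation), with BMF at 1.89 ± 0.06 and BBC3 at 0.87 ± 0.12.

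Whether doxorubicin acted differently after 1035 was asked with the interaction of the 2 treatments, which holds the same unknown about the last 10 h of 1035. It also holds the difference in length of treatment between doxorubicin and DMSO. For 3 genes the rise with doxorubicin was larger after 1035 than without it. NFKBIA rose from 97.3 ± 1.64 to 128 ± 5.34 CPM without 1035 and from 69.7 ± 2.69 to 147 ± 4.76 CPM after it (interaction 0.68 ± 0.09 on the log2 scale, adjusted p = 4.3e-05, edgeR). TNFAIP3 stood at 175 ± 2.99 and 201 ± 1.37 CPM without 1035 and at 188 ± 4.62 and 314 ± 17.7 CPM after it (interaction 0.53 ± 0.08, adjusted p = 0.00112). MIR146A stood at 14.4 ± 2.81 and 14.4 ± 1.69 CPM without 1035 and at 24.7 ± 1.71 and 47.2 ± 0.832 CPM after it (interaction 0.91 ± 0.16, adjusted p = 0.00619). The identifier given for MIR146A belongs in GENCODE release 29 to the long RNA MIR3142HG, which hosts this microRNA, so the counts measure the host transcript and not the mature microRNA. On GRCh38, NFKBIA lies on chromosome 14 from 35401511 to 35404749, TNFAIP3 on chromosome 6 from 137867188 to 137883312 and MIR3142HG on chromosome 5 from 160438594 to 160487426. These 3 positions are the whole annotated genes. No gene was lower in the interaction by edgeR's quasi-likelihood test or by DESeq2, which called 2 higher genes and not MIR146A (0.92, adjusted p = 0.125). The likelihood ratio test called 3 higher and 3 lower, and a replicate block 4 higher and 12 lower. At an unadjusted p under 0.05 edgeR's quasi-likelihood test had 786 genes, 437 of them lower. This is less than the share of 0.05 of the 16320 tested genes that would pass if none had changed.

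CDKN1A had an interaction of 0.03 ± 0.08 and MDM2 of -0.00 ± 0.08 (adjusted p = 0.987 and 1, edgeR). Over the 31 tested p53 target genes, which did not pass singly (1 adjusted over the list alone), the median interaction was 0.06 (bootstrap over genes, 95% interval -0.000569 to 0.173), and camera placed the list up (adjusted p = 0.0168, adjusted p = 0.629 with an estimated correlation). Of 18 NF-kB target genes, NFKBIA and TNFAIP3 passed and 16 did not (3 adjusted over the list alone; camera adjusted p = 0.00164, adjusted p = 0.593 with an estimated correlation). The next smallest adjusted p-values were those of TLE6, with 0 counts in both DMSO libraries, the antisense locus RP11-356I2.4 (-0.57 ± 0.13) and the pseudogene HSP90AB2P (-1.12 ± 0.27), none past the test. HDAC1 (0.08), HDAC2 (0.07), HDAC3 (-0.08), TOP2A (0.06), BCR (-0.02) and ABL1 (-0.03) did not pass either. The genes in the interaction numbered 1 higher and 0 lower without library 2 of DMSO, 3 and 3 without library 1 of 1035, 64 and 175 without library 1 of doxorubicin, and 4 and 2 without library 2 of 1035 and library 2 of doxorubicin together. Calls ended with single libraries left out (edgeR, adjusted p): TNFAIP3 without combination library 2 (0.113) or DMSO library 2 (0.0786), and MIR146A without 1035 library 2 (0.0578), combination library 1 (0.173), combination library 2 (0.197) or DMSO library 2 (0.577).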

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

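The tests of all explanations in this part were chosen only after the result was seen. Whether the effect of doxorubicin differed after 1035 was tested directly, and 3 genes passed. Camera called 10 gene lists at its preset correlation and 0 with an estimated correlation, where their smallest adjusted p was 0.593 (edgeR's model). The genes were NFKBIA (log2 0.68), TNFAIP3 (log2 0.53) and MIR146A (log2 0.91). All had a larger log2 fold change in 1035 then doxorubicin against 1035 than in doxorubicin against DMSO.

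By camera, in edgeR's model, p53 target genes (adjusted p = 0.0168), genes of G1/S and DNA replication (4.0e-06), replication-dependent histones (0.00452), homologous recombination and resection (0.0168), the DNA damage checkpoint (0.0168), NF-kB target genes (0.00164), the unfolded protein and integrated stress response (0.00971) and ribosomal proteins (0.00762) were shifted up in the interaction. Stromal and fibroblast markers (0.00253) and mitochondrially encoded genes (8.1e-07) were shifted down. Library 2 of 1035 and library 2 of doxorubicin, which the interaction subtracts, held more mitochondrial reads than their partners, 0.258% against 0.207% and 0.258% against 0.163%.

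NFKBIA, TNFAIP3 and the host transcript of MIR146A rose more with doxorubicin after 1035 than without it. A larger response of all doxorubicin-responsive genes was examined only in 27 p53 targets. They were higher in the average effect of doxorubicin without and after 1035, a choice independent of the interaction. Their median interaction was 0.0556 (bootstrap over genes, 95% interval -0.000569 to 0.193), against 0.53 to 0.91 in NFKBIA, TNFAIP3 and MIR146A. This argues against a shift of like size in these targets. The interval leaves out error that genes of a library share. A smaller shift stays open, since camera placed the p53 list up (adjusted p = 0.0168), though not with an estimated correlation. A mere effect of the log scale on a lower baseline is argued against for NFKBIA by its increase of 76.9 CPM after 1035 against 30.4 CPM without, 2.53 times as much. Among NFKBIA, TNFAIP3 and MIR146A, NFKBIA alone had fewer CPM in 1035 than in DMSO. An end of exposure to 1035 in the last 10 h was not tested and stays open, as does a change by 1035 of the NF-kB response to doxorubicin as a hypothesis, although 16 of 18 NF-kB target genes did not pass in the interaction, and camera, which called the list (adjusted p = 0.00164), did not with an estimated correlation (adjusted p = 0.593). TNFAIP3 and MIR146A lost their call with single libraries left out, TNFAIP3 without combination library 2 (0.113) or DMSO library 2 (0.0786), and MIR146A without 1035 library 2 (0.0578), combination library 1 (0.173), combination library 2 (0.197) or DMSO library 2 (0.577) (edgeR, adjusted p), and MIR146A also with DESeq2 (0.125).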

How the results depend on the processing

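Leaving out library 2 of 1035 and library 2 of doxorubicin together was chosen only after the data were seen. The genes changed numbered 7993 in 1035 against DMSO, 7156 in 1035 then doxorubicin against doxorubicin and 8022 in 1035 then doxorubicin against DMSO, and stayed within 1.5 times of this in 19 of 20, 18 of 20 and 18 of 19 alternatives. With 1 library left out they ranged from 6403 to 8463, from 5615 to 7295 and from 6495 to 8441. A fold change of at least 2 left 1480, 1192 and 1484, and 16 of 217 in doxorubicin against DMSO, 13 of 81 in 1035 then doxorubicin against 1035 and 0 of 3 in the interaction. The interaction had 2 genes past the FDR in DESeq2. It had 786 at an unadjusted p under 0.05 in edgeR, less than that share of the 16320 tested genes. The authors' deposited adjusted p gave 80 for doxorubicin against DMSO, 37 for the combination against 1035 and 4436 for the combination against doxorubicin. An FDR of 0.01 gave 68 for doxorubicin against DMSO. Fits of the 2 compared groups alone gave 134 for doxorubicin against DMSO and 151 for the combination against 1035. With 1 library left out, doxorubicin against DMSO ranged from 33 (without library 1 of DMSO) to 1180 (without library 1 of doxorubicin), with 65 without library 2 of DMSO, 98 without library 2 of doxorubicin and 116 without either combination library. The combination against 1035 ranged from 30 (without library 2 of the combination) to 143 (without either doxorubicin library), with 45 without library 2 of 1035 and 50 without library 1 of the combination. The interaction ranged from 1 (without library 2 of DMSO) to 239 (without library 1 of doxorubicin, 64 higher and 175 lower), with 6 without library 1 of 1035 (3 higher and 3 lower). It held 6 genes by the likelihood ratio test (3 higher and 3 lower), 16 with a replicate block (4 higher and 12 lower) and 6 (4 higher and 2 lower) without library 2 of 1035 and library 2 of doxorubicin together. Without these 2 libraries the other comparisons, in the order 1035 against DMSO, doxorubicin against DMSO and the combination against 1035, doxorubicin and DMSO, held 7784, 191, 104, 7343 and 8891 genes. The replicate block gave 8108, 299, 92, 7187 and 8060, although the replicate numbers did not pair the samples. Camera with an estimated correlation called 2 of 11 lists in the combination against 1035 and 0 in the other comparisons and the interaction, against 15, 12, 17, 16 and 10. Fry called 25 lists in 1035 against DMSO, 2 in doxorubicin against DMSO, 3 in the combination against 1035 and 0 in the interaction. The Pearson correlation across genes of the 2 responses to 1035 was 0.543, and 0.930 over genes with a mean normalised count of at least 50. It was 0.717 between differences of single libraries, averaged over library 1 of a response with library 2 of the other and the reverse. These differences were of log2 CPM with a prior count of 2, which damps scarce genes. This value, and the 0.130 below, thus differ from the others by estimator as well as by libraries. Without the 2 libraries the correlation of the fold changes was 0.808. That of the 2 responses to doxorubicin was -0.447 and turned positive, at 0.221, 0.130 and 0.0982 in the same order. Reads that are high in library 2 of doxorubicin raise doxorubicin against DMSO. Those high in library 2 of 1035 lower the combination against 1035. An excess that these 2 libraries share thus pushes this correlation down, and it was positive without them. Apart from settings that test fewer genes or samples, the cause was not tested. Of 434 calls of named genes, followed over 7645 combinations of call and setting, 7385 held, 260 were lost and 0 changed sign. At this depth and with 2 libraries per group, 73% of simulated 1.5-fold changes were recovered in the interaction, so that changes of this size can be missed there. That simulation held 200 changed genes, all with a mean normalised count of at least 50, and gave 188 calls. With the 3 calls of the data the FDR sets a stricter limit on p. The share recovered is thus lower in the data than 73%, by an amount that was not measured.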

Other observations

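The gene families and the tests of mitochondrial DNA, of fewer reads in library 2 and of background reads were chosen only after the result was seen. Families other than the fixed lists, although some members are in those lists, were counted by edgeR's test in 1035 against DMSO. Members had a mean count of at least 20, and no family was tested as a whole. Over all genes, 3944 of 16320 rose and 4049 fell in this comparison. These shares changed with abundance. In the tenth of genes with the lowest mean counts 14.7% rose and 3.1% fell, and in the highest 19.4% rose and 46.6% fell. The families here and below were not set against genes of like abundance, so their falls are less distinct than the share over all genes implies. Of 82 mitochondrial ribosomal protein genes, which serve translation inside mitochondria, 41 fell and 4 rose, with MRPL54 at -1.03 ± 0.11 and MRPL48 at -0.86 ± 0.09 on the log2 scale. Among 74 nuclear NDUF, COX and UQCR genes of the respiratory chain, 39 fell and 1 rose, with NDUFB2 at -0.86 ± 0.08 and COX8A at -0.53 ± 0.07. DDX genes, which encode RNA helicases, fell for 24 of 39 and rose for 1, with DDX59 at -0.92 ± 0.11 and DDX54 at -0.61 ± 0.06. In 1035 then doxorubicin against doxorubicin the falls numbered 35, 34 and 14 and the rises 3, 1 and 2 in these 3 families. Without library 2 of 1035 and library 2 of doxorubicin the falls numbered 37, 39 and 25 in 1035 against DMSO and 34, 34 and 19 in the other comparison. Of 22 gamma protocadherin genes, which share exons so that their reads cannot be told apart with certainty, 21 fell in each of these comparisons.

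Other families had more rises than falls in 1035 against DMSO. Of 15 syntaxin genes, which encode proteins of vesicle fusion, 13 rose, with STX1A at 1.57 ± 0.18 and STX6 at 0.42 ± 0.07. They include both STX16 and the overlapping STX16-NPEPL1, whose reads cannot be told apart with certainty. Tetraspanin genes, which encode organisers of the cell membrane, rose for 11 of 19 and fell for 2, with CD82 at 2.66 ± 0.11 and TSPAN15 at 1.81 ± 0.15. Of 12 genes of TNF receptor family members, 6 rose and 1 fell, with TNFRSF1A at 0.81 ± 0.09. Long intergenic RNAs, counted with no minimum, went both ways, with 123 of 591 higher and 68 lower, among them MIAT (3.01 ± 0.08), studied in nervous tissue and heart, and CRNDE (-1.28 ± 0.10). In 1035 then doxorubicin against doxorubicin, 11 syntaxin genes rose, 14 tetraspanin genes rose and 1 fell, and 94 long intergenic RNAs were higher and 60 lower. The counts of each of these families in 1035 against DMSO were the same or differed by 1 with DESeq2's size factors, and without the 2 libraries 14 syntaxin and 12 tetraspanin genes were higher.

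Library 2 of 1035 and library 2 of doxorubicin held more reads on mitochondrial genes of the light strand than their partners, 0.0262% against 0.00307% and 0.0110% against 0.00295% of reads. Fewer reads in library 2 are argued against by the combination, whose shallower library had 0.637 times the share of its partner. Mitochondrial DNA in library 2 of 1035 stays open, because the genes of the heavy strand did not give a single answer. The median excess on MT-CO1, MT-CO2 and MT-CO3 was -0.0797 times that on MT-ND6 per kilobase. These excesses had both signs, negative for MT-CO1 and MT-CO3 and positive for MT-CO2. The share of reads on all heavy-strand genes was higher in library 2 of 1035 than in library 1, 0.231% against 0.204%. In library 2 of doxorubicin the ratio of the median excess on MT-CO1, MT-CO2 and MT-CO3 to that on MT-ND6 was 0.938. This is near the even coverage that DNA gives. Reads spread over the nuclear genome stay open for both libraries, since the share of reads on the tenth of nuclear genes that was scarcest in the other 6 libraries was 1.35 and 1.26 times that of library 1, against 1.05 in DMSO and 1.07 in the combination with their library 2 likewise left out of the choice of genes. No biological explanation was tested, since both libraries of a group had the same treatment.

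After 1035, scarce genes tended higher and abundant genes lower, with a correlation (Spearman, across genes) of mean count and log2 fold change of -0.246 in 1035 against DMSO. In the lowest of 10 equal bins of genes by mean count the median log2 fold change was 0.38 there, but 0.08 (bootstrap 95% interval 0.03 to 0.11) in 1035 then doxorubicin against doxorubicin, below the 0.15 of the second bin. In 1035 then doxorubicin against DMSO, without library 2 of 1035 and library 2 of doxorubicin, it was 0.28 (0.23 to 0.34), above the 0.23 of the second bin. The rise of the lowest bins was thus also seen without these 2 libraries, but background reads stay open for the lowest bins. For the fifth to the top bin they are argued against by the fifth, whose median log2 fold change lay 0.193 above that of the top bin (bootstrap 95% interval 0.162 to 0.224) in 1035 then doxorubicin against DMSO, which uses neither of these 2 libraries. Gene length is argued against by a correlation of -0.196 or stronger in each of 3 bins of genes by length, while the part that the 2 libraries play cannot be told apart, because the correlation was -0.195 without them, between the bounds set for a cause and for none. A candidate explanation that stays open is an effect of 1035 on transcription or RNA stability that depends on a gene's level of expression, which was not tested.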
